A study of Mus musculus with 12 samples.

How the data were processed

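Primary mouse brain microvascular endothelial cells, the cells that line the small vessels of the blood-brain barrier, were grown from newborn C57BL/6 mice, per the labels' protocols. Total RNA was extracted, amplified, labelled with Cy3 and hybridised to a 1-colour Illumina whole-genome mouse BeadChip, 1 array per sample. The 12 arrays fall into 4 groups of 3, defined by 2 treatments: the inflammatory cytokines TNF-alpha and IFN-gamma (inflamed, against naive) and LY-317615 (LY, against control). LY-317615, also known as enzastaurin, is an inhibitor of protein kinase C-beta. It was applied at 5 µM for 8 h, and the cytokines for 24 h. The labels print the concentration of each cytokine as 500 µM, a unit that is unusual for proteins and was not resolved here. Arrays of a group are named 1x, 3x and 3, except in the inflamed control group, where they are named 2x, 3x and 3. The labels call the arrays repetitions of a sample and do not say that they came from separate cultures. The design text counts 2 samples with cytokines and 2 without, which would make each group 1 sample measured on 3 arrays. An n of 3 therefore counts arrays, and p-values measure only the spread between arrays, which may be technical.

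The deposited non-normalized table gives an intensity per probe and array on a linear scale, with no normalization stated. A detection p-value per probe and array stands beside each intensity in the deposited tables. These p-values reach far lower than a rank among negative control probes would allow, so detection at 0.05 is a lenient filter. A second deposited table holds intensities that the authors normalized between arrays. It is also linear, and its method is not given in the sources used here, nor are the scanner software and its background handling. The deposited series matrix held the same normalized intensities for 45281 of the 46237 probes, with 100% of values equal within a small absolute tolerance (1e-06). The medians of the 12 arrays in the normalized table lay between 85.2 and 86.4. Since the series matrix holds the same values, its direction and scale are known and only the normalization method stays unknown.

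The main values were computed from the non-normalized table with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with negative-control parameters inferred from the detection p-values, with an offset of 16, followed by quantile normalization and log2 transformation. The inference reads these p-values as ranks among negative control probes, which their low values put in doubt. The sizes of fold changes and bounds that start near background rest on it. Probes with a detection p under 0.05 on at least 3 arrays were kept, 26521 in all. The platform annotation gave 1 gene symbol for 34885 probes and several for 18, and 11334 probes of the table were not listed in it. All symbols were current by the gene table used. The brightest detected probe of each symbol was tested, 13651 probes in all, and the counts over all 26521 detected probes were computed beside them. One linear model with a mean per group was fitted to all 12 arrays, with 8 residual and 3.36 prior degrees of freedom. It gave 5 contrasts: cytokines without LY, cytokines with LY, LY in naive cells, LY in inflamed cells, and the difference between the last pair (the interaction). Adjusted p-values are limma's moderated p-values after Benjamini-Hochberg adjustment, with 0.05 as threshold. "Called" refers to that threshold. Errors of log2 fold changes are standard errors of that fit, and errors of group means are SDs over 3 arrays.

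The groups, the tests, 32 gene lists, 13 genes to be reported in every contrast and the rule for naming further genes were fixed before the data were examined. That rule takes, per contrast, the 8 highest and 8 lowest called genes whose groups do not overlap, or the 3 with the smallest p where none is called. The gene lists were tested with camera at a preset correlation of 0.01. A joint result for the lists of cytokine-response genes is not reported here. Because the values did not follow the probe identifiers, no called probe is described by a gene symbol. Results for genes and gene lists chosen in advance are given by annotation only, and the naming rule was reduced, after the data were seen, to at most 2 probes that rose and 2 that fell, given by identifier. The check of identifiers compared the mean signal of 2 probes annotated to the same gene, over 9172 genes, with 1000 shuffles of the identifiers, and the row positions of gene classes with 10000 permutations, using Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

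Arrays of the non-normalized table were matched to those of the normalized table by the correlation of log2 signals centred per probe. The names of the non-normalized table were used throughout, as planned. Results that involve inflamed cells were also computed with 2 array names exchanged and with both arrays left out. Same-numbered arrays were checked for pairing through the correlation of their deviations from the group means. The 3 pairs of naive control and naive LY arrays gave 0.258 to 0.399, so the numbers were taken to pair these groups, from the data alone. The highest value came from the arrays named 3, which stood apart in all groups, so there pairing cannot be told from that difference. Between the x arrays of these groups, same numbers gave 0.258 and 0.316, and different numbers -0.0293 and -0.0867. Of the other groups compared, inflamed control shares only 2 numbers with each, and the lowest correlations of inflamed LY were 0.0535 with naive LY and 0.0747 with naive control. With the names exchanged, the 3 pairs gave 0.198 to 0.331 with naive LY and 0.134 to 0.310 with naive control, so the numbers would pair these groups too, and a blocked fit under the exchanged names was added.

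The fit was tested on simulated data with 200 changed probes of 13651. In the contrast of cytokines without LY it recovered 8.96% of 1.5-fold, 43.9% of 2-fold and 86.2% of 4-fold changes, with an average of 4.8 false calls among 97.1. For LY in naive cells, 7.31%, 45.2% and 86.2% were recovered, and for LY in inflamed cells 7.91%, 44.0% and 87.1%. The number of arrays limits the precision. Alternatives covered the background correction, the normalization, the authors' normalized values, the filter on dim probes, averaging of probes, the arrays in the fit, replicate labels as a block or random effect, averaging of arrays 3 and 3x, the suffix x as a block, array weights, the variance model and leaving out each array. Alternatives that concern array names, the suffix x alone and all detected probes were added after the data were seen. The median LY effect on cytokine-induced probes was first judged across alternatives by its SD over simulations. That yardstick was replaced by the SD between arrays after the alternatives had been seen, and the outcome of both is given with the alternatives.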

Results

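Gene expression was measured in primary mouse brain microvascular endothelial cells on 12 arrays, 3 in each of 4 groups: naive control, naive LY, inflamed control and inflamed LY. The series addresses what inhibition of protein kinase C-beta does to transcription in these cells, in a resting state and after exposure to TNF-alpha and IFN-gamma. Between 42.5% and 51.1% of the 46237 probes were detected per array. The mean signal per array lay between 133 and 156 and the median between 83.1 and 88.4, with the brightest probe of an array between 15410 and 19926. The lowest signal on any array was 66.3, so most probes lay close to background. After background correction and quantile normalization, arrays of the same group differed by a median of 0.11 to 0.15 per probe on the log2 scale. That median runs over all 46237 probes, most of them dim, and says little about bright ones.

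The first question for any gene-level statement was whether the values belong to the probes beside which they stand. Probes annotated to the same gene showed no shared level. Over 9172 genes with at least 2 probes, the correlation of mean log2 signal between 2 probes of a gene was -0.00305 (Spearman's rho -0.0126), inside the -0.0295 to 0.0324 given by 1000 shuffles of the identifiers. Their cytokine responses were equally unrelated, with r = 0.00343 against -0.0314 to 0.0369 in shuffles. These correlations run across genes, which are not independent replicates. Probes annotated to genes that nearly all cells use at high levels were dim in part. The 5 probes of Actb, which encodes beta-actin, and the 1 probe of the glycolytic enzyme gene Gapdh had mean signals of 79.4 to 92.3, none above the 65.5th percentile of all probes. Of the probes of other such genes, 1 of Tmsb4x had a signal of 287, at the 93.5th percentile, and its other probe 81.5. Ribosomal protein genes, with 96 probes, had a median signal of 84.5, and 21.9% of these probes were detected on all arrays. Olfactory receptor genes, which are largely restricted to sensory neurons, had a median of 85.5 over 1287 probes with 27.7% detected, against 85.3 and 27.3% over all probes.

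**Figure D1:**
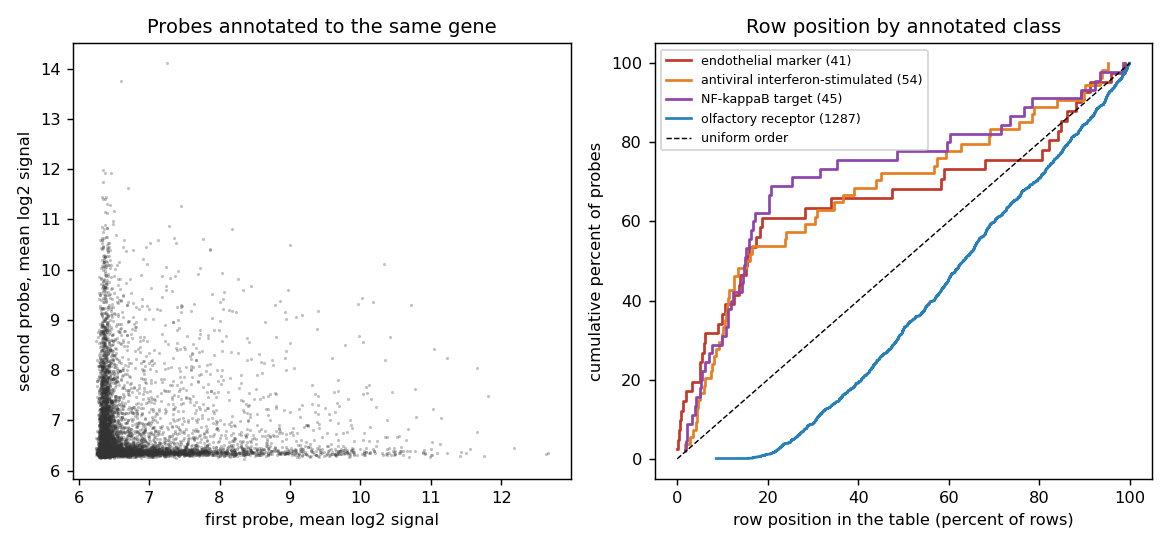
Left, mean log2 signal over the 12 arrays of 2 probes annotated to the same gene, 1 point for each of 9172 genes; bright probes of a gene are paired with dim ones, and r is -0.00305. Right, cumulative percentage of the probes of 4 gene classes against their row position in the table, as a percentage of all rows; endothelial markers lie early (median 15.4%) and olfactory receptors late (median 63.2%), and the dashed line is a uniform order.

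The planned gene-level results were computed all the same and fell at the level of arbitrary probes. Over all 32 lists, 24 of 488 list memberships were called under cytokines without LY, or 4.92%, against 4.79% of all probes tested. A probe that belongs to several lists is counted in each of them. None of the lists was called by camera in any of the 5 contrasts, with a preset or an estimated correlation. The smallest adjusted p was 0.0557, for LY in naive cells, and 0.874 for cytokines without LY. The self-contained test fry called 1 list in LY in naive cells (adjusted p = 0.0319), tight and adherens junctions, with a median of 0.14 over 28 measured members; camera with an estimated correlation gave an adjusted p = 0.248 for it. Of the 13 genes chosen in advance, 11 were tested, and none of their 55 comparisons was called. The probe annotated to Prkcb, the gene of the kinase that LY inhibits, gave 0.20 ± 0.41 (SE, adjusted p = 0.895) under cytokines without LY. These values are attached to identifiers that the data did not bear out and describe no gene. The responses below are therefore described by probe.

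Array names were compared between the deposited tables. Of 12 arrays, 10 had their best match under their own name, the lowest of them at r = 0.916. The inflamed control array 2x and the inflamed LY array 1x matched each other. The non-normalized control 2x correlated at 0.998 with the normalized LY 1x, and the non-normalized LY 1x at 0.949 with the normalized control 2x, against 0.161 and 0.144 under their own names. Both are inflamed arrays, so the exchange leaves the naive and inflamed sets intact and bears on each contrast that separates LY from control in inflamed cells. Values with the names exchanged are given beside the results it moves.

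**Figure D2:**
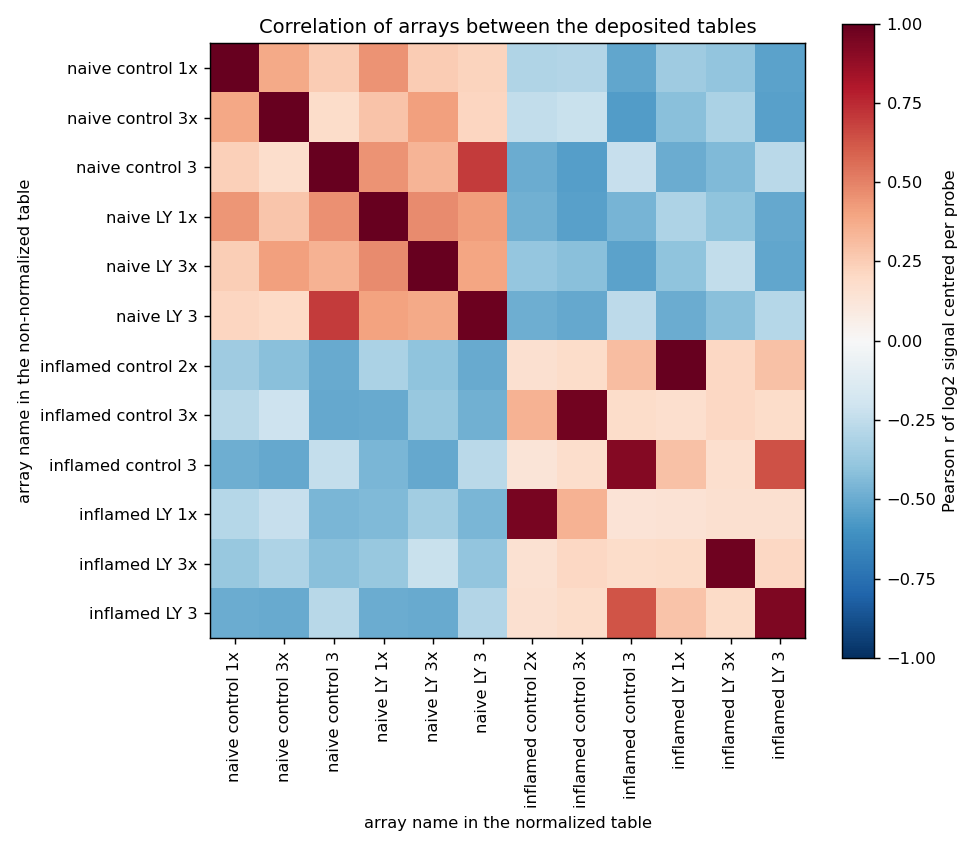
Pearson correlation, across probes, of log2 signal centred per probe between each array of the non-normalized table and each array of the normalized table, labelled by group and array name. The diagonal holds the best match for 10 arrays; inflamed control 2x and inflamed LY 1x match across names, at 0.998 and 0.949.

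Cytokines without LY, inflamed control against naive control, asked how the cells responded to inflammation. Many probes changed, and more rose than fell. Of 13651 probes tested, 396 were called higher and 258 lower in inflamed cells, with a median absolute log2 fold change of 1.37 among the 654. More than 2-fold changes were seen in 318 of the higher and 183 of the lower probes. At an unadjusted p under 0.05 there were 2181 probes, against 682.55 expected by chance. Over all 26521 detected probes, 627 were higher and 411 lower. The largest log2 rise among them was 7.73. Among the 13651 probes tested, 1 per gene symbol, the largest rise was that of probe ILMN_1230900, from 4.41 ± 0.03 in naive control to 10.82 ± 0.28 in inflamed control (log2, SD, n = 3), a difference of 6.40 ± 0.22 (SE, limma adjusted p = 1.92e-08). It was detected on 2 of 3 naive control arrays. Probe ILMN_1231231 rose by 6.28 ± 0.22, from 4.39 ± 0.42 to 10.67 ± 0.15, and was detected on 1 of 3 naive control arrays. Set against the lowest detected signals of those arrays, its rise was at least 6.23. The largest fall was that of probe ILMN_2676243, from 9.54 ± 0.94 to 5.91 ± 0.57, a log2 fold change of -3.63 ± 0.55 (adjusted p = 0.00284). Probe ILMN_2786125 followed, at -3.22 ± 0.44 (adjusted p = 0.00143).

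The count of 654 fell when any array of the contrast was left out, which also leaves 2 arrays in a group. It was 382 without naive control 1x (274 higher and 108 lower, so that the lower calls dropped more), 425 without naive control 3x and 432 without inflamed control 2x. Leaving out another array of the contrast gave 518 to 578. Leaving out a naive LY array, which is not part of the contrast, gave 548 to 567. The count was 393 with arrays 3 and 3x averaged and 355 with only the groups of the contrast. With the 2 inflamed names exchanged, 391 probes were higher and 234 lower, and with both of these arrays left out 493 were called.

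**Figure D3:**
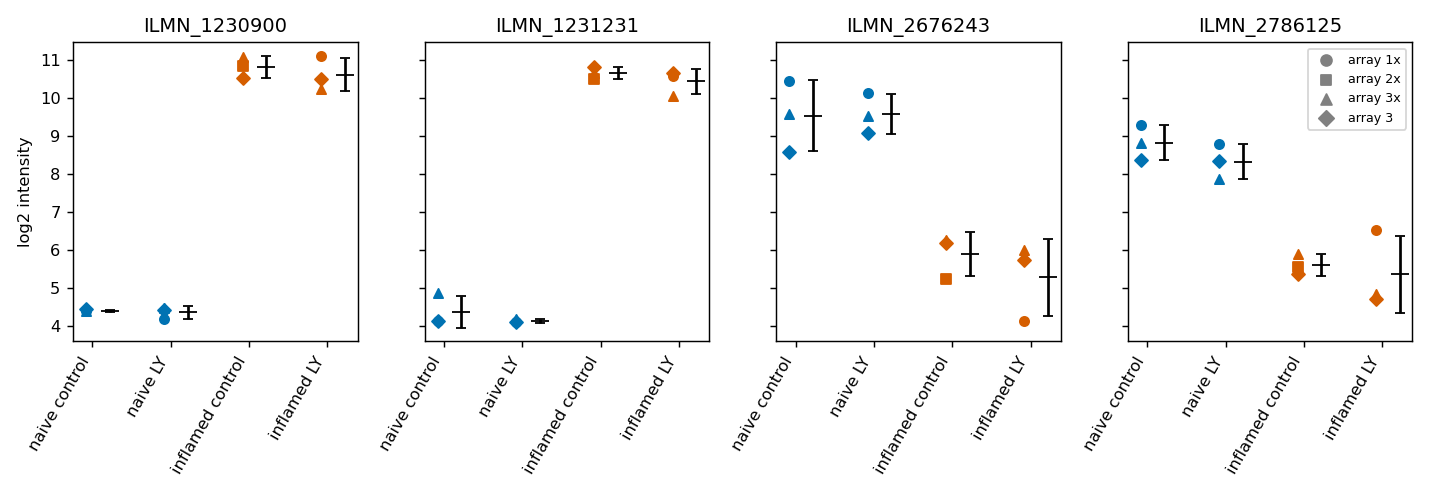
Log2 intensity of 4 probes on each of the 12 arrays by group; symbols mark the array name, blue naive and orange inflamed, and the black bars show the mean ± SD of 3 arrays. Probes ILMN_1230900 and ILMN_1231231 were higher and ILMN_2676243 and ILMN_2786125 lower on inflamed control than on naive control arrays.

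Cytokines with LY, inflamed LY against naive LY, gave the same comparison in cells exposed to the inhibitor, on a separate set of 6 arrays. Here 323 probes were called higher and 190 lower, 263 and 135 of them by more than 2-fold, with 2064 at an unadjusted p under 0.05. Among these 13651 probes, ILMN_1230900 rose by 6.25 ± 0.22 (adjusted p = 1.85e-08) and was detected on 2 of 3 naive LY arrays. ILMN_1231231 was not detected on any naive LY array and was at least 75.0-fold higher in inflamed LY when set against the lowest detected signals of those arrays (adjusted p = 1.85e-08). ILMN_2676243 fell by 4.29 ± 0.55 (adjusted p = 0.00113) and was detected on 2 of 3 inflamed LY arrays. Set against the lowest detected signals of those arrays, its fall was at least 4.25. Over all detected probes 534 were higher and 299 lower, and the largest log2 rise was 7.47. The count of 513 was 251 with arrays 3 and 3x averaged (181 higher and 70 lower). It was 279 without naive LY 1x (214 higher and 65 lower), 325 without naive LY 3x and 317 without naive LY 3. It was 419 with both doubtful arrays left out, 577 with the names exchanged, and 841 with the array number as a block as well, 440 higher and 401 lower. Under the exchanged names the numbers would pair these groups.

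Both cytokine contrasts shared no arrays, and their calls overlapped widely. A total of 370 probes were called in both, 268 higher and 102 lower, and none in opposite directions. Independent lists of these sizes would share 9.37 higher and 3.59 lower probes. These contrasts are not strictly independent. The array numbers were taken to pair naive control with naive LY, and the same fit gave the spread of each probe in both. Shared deviations of this kind can raise the overlap above these numbers. Of the 654 probes called without LY, 642 (98.2%) had the same sign with LY. Across all 13651 probes the fold changes correlated at r = 0.737 and rho = 0.500. Over the probes called without LY the slope of the effect with LY on the effect without it was 0.877. Choosing probes by their effect without LY can itself pull this slope under 1, so it does not measure a damping by LY. With the names exchanged, 393 probes were shared and r was 0.759. The 4 arrays named 3 and the 8 named with an x gave the same directions separately. Of 237 probes called on the x arrays without LY, 228 (96.2%) had the same sign on the arrays 3. The median of the higher probes was 2.11 on the x arrays and 2.27 on arrays 3, and that of the lower probes -1.84 and -0.97. With LY, 135 of 139 (97.1%) had the same sign. With the names exchanged it was 288 of 301 (95.7%) without LY and 225 of 228 (98.7%) with LY. Arrays 3 give a single array per group, and the arrays of a group may be repetitions of the same sample. This agreement therefore shows that arrays repeat each other and does not replicate the cytokine response in separate cultures.

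**Figure D4:**
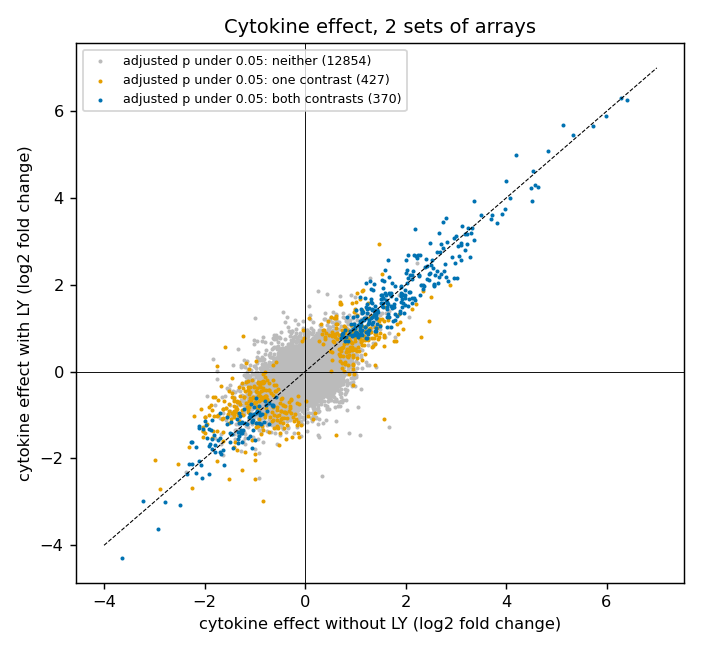
Log2 fold change of inflamed over naive arrays without LY (horizontal) and with LY (vertical) for the 13651 probes tested, coloured by whether the adjusted p was under 0.05 in both contrasts (370 probes), in 1 or in neither. The dashed line marks equal effects; no probe was called in opposite directions.

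LY in naive cells, naive LY against naive control, asked what the inhibitor did without inflammation. No probe of 13651 was called by limma, and 351 had an unadjusted p under 0.05, against 682.55 expected by chance. In the bin of p from 0.95 up there were 830 probes, so p-values ran high and the test was conservative here. The fit leaves out the pairing that the array numbers were taken to give these groups. The smallest adjusted p was 0.999977. The median 95% interval of a probe's log2 fold change had a half-width of 0.50. For 11131 probes (81.5%) the interval excluded a 2-fold change of intensity in either direction. The offset of 16 shrinks the fold changes of dim probes, so for these a 2-fold change of RNA is not excluded. Over all detected probes no call was made either, with 680 probes at an unadjusted p under 0.05. With the array number as a block, for the numbers taken to pair these groups, the count was also 0.

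LY in inflamed cells, inflamed LY against inflamed control, gave no call by limma, with 656 probes at an unadjusted p under 0.05 and a smallest adjusted p of 0.881. The interval excluded a 2-fold change of intensity for 10697 probes (78.4%), with the same limit for dim probes. The count was also 0 with the names exchanged. On the 8 x arrays alone with the names exchanged, 4 probes were called, 1 higher and 3 lower; 2 of the lower were ILMN_2619983 (-2.91 ± 0.23, adjusted p = 0.0370) and ILMN_2686029 (-2.66 ± 0.22, adjusted p = 0.0370). Over all 12 arrays under the unexchanged names the same probes gave 0.34 and -0.08, both with an adjusted p of 0.999. They were picked after their values were seen.

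**Figure D5:**
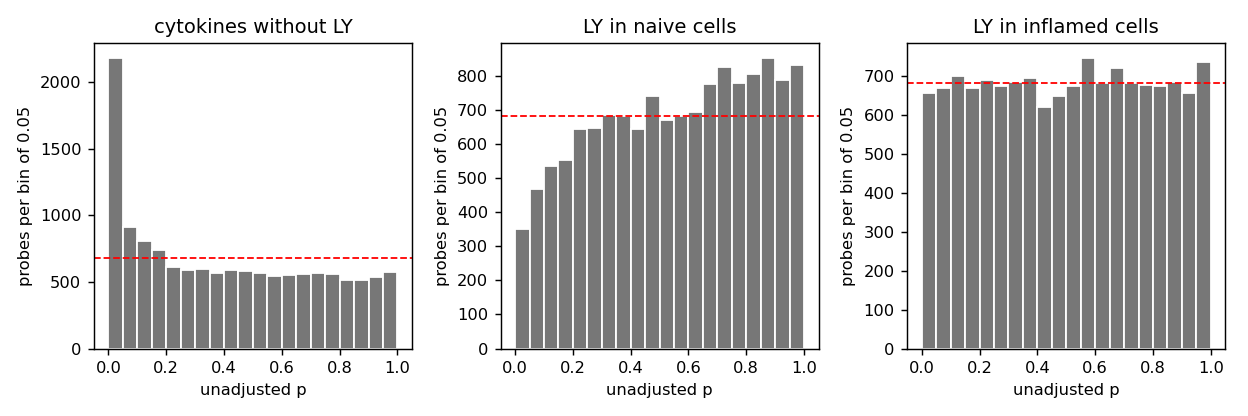
Number of probes per bin of 0.05 of the unadjusted limma p in 3 contrasts, over 13651 probes, with the red dashed line at the number expected by chance. The first bin holds 2181 probes for cytokines without LY, 351 for LY in naive cells and 656 for LY in inflamed cells.

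The test of whether the LY effect differed between inflamed and naive cells, the interaction, gave no call by limma, with 457 probes at an unadjusted p under 0.05 and a smallest adjusted p of 0.711. The interval excluded a 2-fold difference of intensity for 53.3% of probes, fewer than for either LY contrast alone, again with that limit for dim probes. LY effects in naive and inflamed cells, which share no arrays, correlated across probes at r = 0.0104 (rho 0.0109). Of 100 splits of the arrays within the naive and the inflamed set, 88 gave a correlation at least as large in size, and the highest was 0.408. Among the 40 of them that part every pair of naive arrays the highest was 0.218, and 33 were as large. The correlation was 0.189 with the names exchanged, 0.141 with both of these arrays left out, 0.139 with the array number as a block and 0.255 in the authors' normalized table.

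Probes induced by cytokines at least 2-fold were examined for a joint shift with LY in inflamed cells. Among the 318 called without LY the median LY effect was -0.14, with 228 lower, and the medians of the 3 inflamed LY arrays ran from -0.26 to -0.02 (SD 0.12). Among the 263 called with LY it was -0.07, with array medians from -0.19 to 0.00 (SD 0.11). The choice of probes favours a negative value in the first set and a positive one in the second, since each uses arrays of the LY comparison. In 100 simulations without an LY effect the medians were -0.11 to -0.03 and 0.03 to 0.12, and none of the 100 was as low as the measured median in either set. These simulations leave out shifts that all probes of an array share, which the array medians contain. With the names exchanged the medians were -0.08 for 309 probes and 0.03 for 274, for which no simulation was run, and with median scaling -0.04 and 0.03. Median scaling also moved the median LY effect of all tested probes in inflamed cells to 0.05, from 0.002 with quantile normalization. For 340 probes chosen by both cytokine contrasts together, a choice made after the data were seen that favours neither sign, the median was -0.12. The exact permutation test over the 10 splits of the 6 inflamed arrays, two-sided, gave p = 0.1, the smallest these splits allow, with 0.12 as the largest size among the other splits. With the names exchanged the median was -0.01 and the exact permutation p = 1. Measured from 0, the shifts of the first and the jointly chosen set were larger than 1 SD between arrays (0.12 and 0.11), and that of the second set was smaller. The choice of probes alone centred the simulated medians on -0.07 in the first set and 0.07 in the second. Distance from 0 therefore does not measure an LY effect in either of these sets. With the names exchanged all 3 shifts from 0 were smaller than their SD between arrays (0.14, 0.16 and 0.17).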

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

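The tests of row order, of a constant displacement, of a missing cytokine response and of a batch shared by the groups, the 9 choices of naive arrays, the 40 splits, and the array signals set beside the batch were chosen only after the results they concern had been seen. Of 6486 detected probes without a single gene symbol, which the gene-level comparisons did not use, 264 changed with cytokines without LY, 156 of them higher. That is 4.07%, against 3.86% of the 20035 detected probes with a symbol. Since values did not follow the identifiers, this division of the probes is arbitrary and says nothing about unannotated transcripts.

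The values did not follow the probe identifiers. A missing cytokine response could leave the responses of same-gene probes unrelated, but not their signal levels, so it could account for only part of the pattern. It would also leave inflamed and naive arrays alike. The 654 calls of the real grouping argue against that, since the other 9 splits of the same 6 arrays gave 1 call at most. Each group may be 1 sample on 3 arrays, so these calls cannot tie the difference to the cytokines. A displacement of all values by a constant number of rows is argued against by a scan of 46237 displacements, whose highest same-gene correlation, 0.0531, lay within the 0.0415 to 0.0543 reached in 10 scans of shuffled identifiers. A different row order of identifiers and values remains as a candidate explanation, while the identifiers themselves stood in an order tied to gene class. The same-gene correlation of -0.00305 is the pattern to be explained and so is no test of this explanation. Endothelial markers had a median row position of 15.4% of the table, NF-kappaB targets 15.1% and olfactory receptors 63.2% (permutation p = 0.0001 each, the smallest possible), although row position and mean signal correlated at a rho of only -0.0316. No biological explanation was tested, and the original order was not recovered.

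Inflamed control 2x and inflamed LY 1x carried each other's values across the deposited tables. To ask which table holds the right names, the LY difference of this pair was correlated with that of the other inflamed arrays, which gave -0.0747, while the first pair of naive arrays gave 0.190. The prediction for wrong names in the non-normalized table asked for a negative value and was met, but all 9 choices of 1 control and 1 LY array among the naive arrays, whose names are not in doubt, gave -0.269 to 0.208, so right and wrong names cannot be told apart by this test. Exchanging the names raised the lowest same-number correlation of naive LY with inflamed LY from 0.0535 to 0.198 and lowered that of naive control 3x with inflamed control 3x from 0.218 to 0.175. It also raised the correlation of LY effects between naive and inflamed cells from 0.0104 to 0.189, a size reached by 5 of the 40 splits that part every pair of naive arrays (highest 0.218).

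The 4 arrays named 3 stood apart from the 8 named with an x. Between these sets 349 probes were called, 286 higher and 63 lower on arrays 3. The difference correlated positively between every pair of groups, from 0.293 to 0.424, consistent with a batch shared by all 4 groups. Brighter arrays that lift dim probes over background had mixed evidence: arrays 3 had the lowest mean signal of their group in 3 of 4 groups, and 24.1% of the called probes lay in the brightest 25% of probes, about the share that no link to brightness gives, but the percentage of probes detected was highest on array 3 in all 4 groups. Each group holds 1 array 3 and 2 x arrays, and with the suffix as a block the cytokine counts were 771 and 631 and those for LY stayed at 0. No biological explanation was tested, since the labels give no meaning to the suffix.

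Other splits of the arrays were refitted for each count. With 10 splits of 6 arrays no share under 0.05 can be reached. For cytokines without LY, 1 of 10 splits (the real one) gave as many calls, 654 against 1 at most in the others; for cytokines with LY it was also 1 of 10, with 513 against 0. For LY in naive cells all 10 splits gave at least the real 0, and the others gave 0. For LY in inflamed cells all 10 did, and the highest of the others was 9. That split sets control 3x, LY 1x and LY 3x against control 2x and both arrays 3, so it partly follows the arrays named 3; with the suffix as a block the real count was 0. For the interaction, 100 of 100 splits drawn gave at least the real 0, the highest being 10. A real count of 0 fixes these outcomes for both LY contrasts and the interaction, so they decide nothing about chance.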

How the results depend on the processing

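The alternatives on array names, the x arrays alone, all detected probes and the naive arrays alone were chosen after the data were seen. In all alternatives both cytokine contrasts gave more higher than lower probes, and each of the 4 named probes kept its sign and its call wherever it was the probe tested for its symbol. The counts without and with LY (main 654 and 513) were 393 and 251 with arrays 3 and 3x averaged, 237 and 139 on the x arrays, 301 and 228 on the x arrays with the 2 names exchanged, and 1038 and 833 over all detected probes. Fewer arrays, or more probes, enter these. With only the groups of the contrast, the count without LY was 355. Leaving out 1 array gave 382 to 686 without LY and 279 to 575 with LY. Without background correction the counts were 706 without LY and 564 with LY. LY in naive cells and the interaction gave 0 in all alternatives run, and LY in inflamed cells 0 except for 4 on the x arrays with names exchanged. With the replicate number as a block the cytokine counts were 464 and 732, those for LY 0, and no list was called; with names exchanged as well, an alternative added later, they were 542 and 841 and those for LY 0; for the pairs of naive cells the block changed no call.

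The median LY effect on induced probes (-0.14 and -0.07) became -0.26 and 0.10 on the x arrays with names exchanged, the only alternative that moved it by over 1 SD between arrays (0.12 and 0.11). By the earlier yardstick, the SD over simulations (0.02 for each), 18 and 16 of 34 alternatives moved it. It was below 0 in 34 of 34 for the first set. The choice of these probes alone gave -0.11 to -0.03 in simulations without an LY effect, so that sign does not show an LY effect. For the second set it was below 0 in 27 and above in 7, so the sign of the second depends on the setting. The settings above 0 include median scaling, which also moved the median of all tested probes up. Leaving out 1 array gave -0.20 to -0.07 and -0.11 to 0.02. The correlation of LY effects was 0.255 in the authors' normalized table and in the series matrix, which carry the exchanged names, 0.189 with names exchanged, with or without the suffix block, 0.194 with names exchanged and the replicate block, and 0.228 on the x arrays with names exchanged; leaving out 1 array gave -0.0889 to 0.0904. Gene lists called went from 0 to 1 with no filter, with arrays 3 and 3x averaged and with fry, and were 0 to 1 on leaving out 1 array. The probe annotated to Cdh5 was called under cytokines without LY with arrays 3 and 3x averaged and on the x arrays alone. The cause was not tested. Lists with a random replicate effect were not run. The low signal over background, with most probes near the median of 83.1 to 88.4, limits what dim probes can show.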

Other observations

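The tests of row position were chosen only after the order of the identifiers had been seen. Mean signals of further abundant transcripts were read by identifier. The 3 probes annotated to B2m, the light chain of MHC class I, had signals of 90.9, 99.8 and 82.9, and the 3 annotated to the elongation factor gene Eef1a1 had 145, 89.6 and 86.3. The 2 annotated to the actin-binding peptide gene Tmsb4x had 287 and 81.5, and the 2 annotated to the ribosomal protein gene Rps3 84.1 and 84.6. Neuron markers stood at a median row position of 65.9% (permutation p = 0.0567), fibroblast markers at 62.0% (p = 0.180), microglia markers at 62.7% (p = 0.177), SRF and YAP targets at 21.8% (p = 0.0002) and antiviral interferon-stimulated genes at 15.7% (p = 0.0001, the smallest possible). Ribosomal protein genes lay at 39.8% (permutation p = 0.0408) and probes without a single annotated symbol at 58.6% (permutation p = 0.0001). These are 10 classes tested in 1 family, without adjustment.

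The first component of the 12 arrays held 36.0% of the variance and separated naive from inflamed arrays, at -31.4 to -26.2 and 25.2 to 32.9. The second held 14.9%, with the 4 arrays named 3 at its low end, -26.9 to -18.6. On the third component, 10.3%, inflamed control 2x lay at -44.7, and the other arrays between -10.8 and 17.4.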
